A study of Rattus norvegicus with 10 samples.

How the data were processed

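RNA from the left ventricle of Sabra rats had been extracted as total RNA with Tri-reagent, labelled with biotin and hybridised to expression arrays, 1 array for each pool, per the labels. The deposited table held 27342 probe sets on 10 arrays with values that the authors gave on a log2 scale, as judged from the values themselves and from their agreement with the fold table. The method of summary and normalization behind these values is not given in the sources used here. A second deposited table held the authors' signed fold change against control for 651 probe sets, read as a score that is negative for lower values, and how its probe sets were chosen is not given in the sources used here. In the value table, columns not used numbered 0.

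Gene symbols came from the deposited annotation of the probe sets and were brought up to date with a table of rat RefSeq genes (assembly GRCr8), which served for names alone, so that no coordinates are given. Of the probe sets, 15097 carried 1 gene symbol, 323 several and 11922 none, and 15067 of the single-symbol probe sets had a gene identifier found in the RefSeq table. For the 499 genes with more than 1 probe set the brightest was kept, which left 14324 genes. Hspa1a, Hspa1b and Hspa1l share a probe set with several symbols and were not tested as genes. Probe sets without a single symbol were tested apart. Arrays do not count molecules, so the number of arrays limits the precision, and low signals lie near the background of the platform.

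Values were quantile normalized across the 10 arrays, because the columns did not have equal distributions. Groups and replicates were taken from the sample labels, with 2 separate pools in each of 5 groups. A linear model with a mean per group was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), which left 5 residual degrees of freedom and added 8.3 prior degrees of freedom. The 8 comparisons were each of the 4 heat-history groups against control, ReAC against DeAC, DeAC against AC30, ReAC against AC30, and the second heat response (ReAC minus DeAC) minus the first (AC2d minus control). An F test asked which genes differed among the 5 groups. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg within a comparison, and a gene passed at an adjusted p under 0.05. The unadjusted counts also used 0.05.

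Of 39 gene lists for pathways, complexes and cell types, 38 had at least 5 measured members and were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera was repeated with an estimated correlation, and fry was run beside it. Member counts were taken over all genes and again adjusted over the list alone. The list of microRNA genes had 0 measured members. The pattern used for ribosomal proteins also caught 6 kinases whose symbols begin alike. The lists, comparisons, tests, alternatives and rule for named genes were fixed before the data were examined. That rule took, in each comparison, up to 6 genes per direction with the largest change among genes that passed and whose pools did not overlap between the groups (3 per direction for DeAC and ReAC against AC30), up to 4 members with the smallest p from each called list and from the lists of the study's own pathways, and a fixed set that included Parp1, Mapk14, Akt1, Stat3, Hspa8, Hsp90aa1, Myh6 and Myh7.

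The alternatives were the values as deposited, median scaling of each array, eBayes without the trend, leaving out the 40% dimmest genes, all probe sets uncollapsed, the mean of a gene's probe sets, the groups of a comparison fitted alone, a replicate block, other thresholds, and each array left out in turn. In the last of these the single pool left in a group was assumed to vary like the pools of the other groups. A fit with the mean atrial marker level of each array as a covariate and a second list of fat genes (16 written, 14 measured) were chosen after seeing the data. The slope of that covariate rests on differences between pools within a group, which for the atrial markers were largest between the control pools. On simulated data for AC2d against control with 14324 genes and 200 changed genes in each of 5 runs, the fit recovered 78.6% of changes of 0.5 log2 units and 100% of changes of 1 log2 unit, 6.69% of its calls were false, and 0 calls had the wrong sign. Comparisons with the same control share its error. In 20 simulated data sets without any effect, the AC30 and DeAC changes had a mean correlation of 0.501 across genes and a mean covariance of 0.00569. For the AC30 calls that went the opposite way in DeAC against AC30, 20 further data sets were simulated around the observed group means with the AC30 mean also given to DeAC. These means include measurement error, so they gave more AC30 calls (a mean of 2420) than the real data. This simulation was added after the real count was seen.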

Results

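Gene expression in the left ventricle of Sabra rats was measured on 10 expression arrays, 2 for each of 5 groups, and each array was hybridised with RNA from a separate biological pool of 5 animals. Untreated rats (control) were 1 month old. The heat groups entered a chamber at 34 °C when they were 3 weeks old. The AC2d group stayed there for 2 days and was 1 month old at sampling, and the AC30 group stayed for 30 days and was 2 months old. The deacclimated group (DeAC) had 30 days of heat and then 30 days at 24 °C, and the reacclimated group (ReAC) went back to 34 °C for 2 more days after that, both being sampled at 3 months. Age, labelled in whole months, therefore matched in AC2d against control and in ReAC against DeAC. The other comparisons joined heat history with a difference in age. The median log2 signal of an array lay between 5.95 and 6.10. Errors are standard errors of the log2 change, every group mean had n = 2 pools, and the small number of arrays limits the precision of each value. Each error came from 1 moderated spread per gene over all 10 arrays. The errors and p-values thus assume an equal spread in all groups and do not measure the spread of the pools compared.

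Myh7, the slow heart myosin heavy chain, was above control in each of the 4 heat-history groups, and the cell cycle genes Top2a and Prc1 were below it in each. Of 14324 genes, 3175 (22.2%) differed among the 5 groups (limma moderated F test, adjusted p under 0.05). Several genes made mainly in the atrium differed between arrays. Sarcolipin (Sln) had a log2 signal of 11.94 and 9.23 in the control pools, 12.96 and 12.78 in the AC30 pools, and 5.79 and 5.73 in the DeAC pools. The myosin light chain Myl7 had 13.20 and 10.97 in the control pools and 8.19 and 8.13 in the DeAC pools. The brown fat gene Ucp1 had 8.43 in control replicate 1 and 4.50 in control replicate 2, and 7.06 and 7.00 in the AC30 pools. The control pools lay more than 1 log2 unit apart for 57 genes, against at most 1 gene in any other group. For such genes the shared spread can understate the error against control and overstate it between the other groups. The first principal component held 39.2% of the variance and the second 19.5%.

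**Figure D1:**
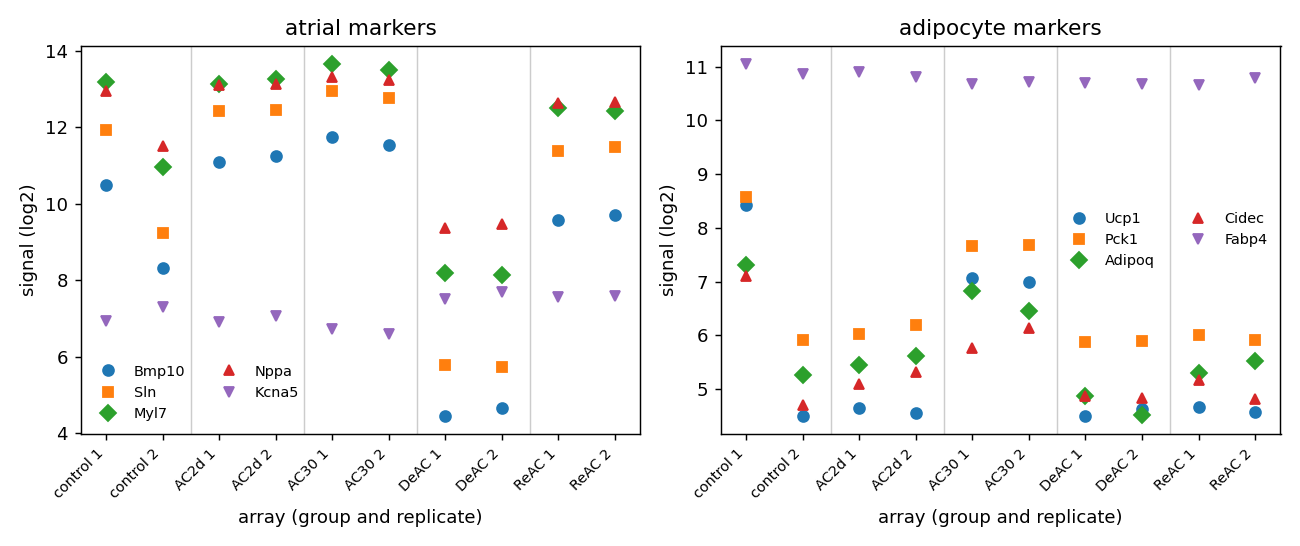
Log2 signal (vertical axis) of 5 atrial and 5 adipocyte marker genes on each of the 10 arrays (horizontal axis), with a point for each gene and pool. The DeAC pools lay lowest for Sln (5.79 and 5.73), and Ucp1 was high in control replicate 1 (8.43) and both AC30 pools (7.06 and 7.00).

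The first 2 days of heat were compared with untreated rats of the same labelled age to ask which genes respond early. The imprinted noncoding RNA H19 rose by 1.78 ± 0.09 log2 units (n = 2 pools per group, adjusted p = 2.12e-07) and Myh7 rose by 1.30 ± 0.11 (adjusted p = 4.52e-05). Epyc, a small proteoglycan, rose by 1.38 ± 0.13, and Sfrp2, a secreted Wnt modulator, by 1.15 ± 0.15. The DNA topoisomerase Top2a fell by 1.55 ± 0.11 (adjusted p = 1.16e-05), the inhibin subunit gene Inha by 1.52 ± 0.09, and the linker histone gene H1f5 by 1.49 ± 0.12. Of 34 measured cell cycle genes, 21 fell and 13 did not pass, and 27 fell when adjusted over the list alone. Among them the cytokinesis gene Prc1 fell by 1.29 ± 0.13, Kif23 by 1.13 ± 0.13 and the nucleotide reductase subunit Rrm2 by 1.00 ± 0.12. Of 22 core histone genes, 7 fell and 15 did not pass, with H2ac4 at -0.90 ± 0.11 and H2bc18 at -0.75 ± 0.10, and 8 fell and 1 rose adjusted over the list alone. Both linker histone genes that passed, of 5 measured, fell (H1f1 at -1.09 ± 0.10), and the same 2 passed adjusted over the list alone. Of 21 glycolysis genes, 5 fell, 1 rose and 15 did not pass, with 12 falling adjusted over the list alone, and the regulator of phosphofructokinase Pfkfb2 fell by 0.65 ± 0.07.

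After the same 2 days, of 27 measured cytosolic and mitochondrial heat shock genes, 4 rose and 1 fell, with 7 rising and 1 falling when adjusted over the list alone, and the chaperone Hsph1 rose by 0.48 ± 0.08 (adjusted p = 0.00412, but 0.0947 without AC2d replicate 2). The count of 4 became 1 without AC2d replicate 1, 0 without AC2d replicate 2 and 2 without control replicate 2. Hsp90aa1 (0.13, adjusted p = 0.242) and Hspa8 (0.05) did not pass. Pdk4, which restrains glucose oxidation, fell by 0.79 ± 0.08 and the mitochondrial carrier Ucp2 by 0.40 ± 0.05, and these were among 3 of 28 fatty acid oxidation genes that fell, or 8 adjusted over the list alone and 8 over all genes without control replicate 1. The zinc finger gene Zbtb16 fell by 0.42 ± 0.05 with 4 other genes of the 18 on the glucocorticoid-responsive list (6 fell and 1 rose adjusted over the list alone). That count of 5 lay between 2 and 6 when single arrays were left out. Of 76 genes matching the pattern for ribosomal proteins, 4 rose and 14 rose adjusted over the list alone. The 4 included Rps6ka2, which is a kinase and not part of the ribosome, and without either AC2d pool 0 passed. Poly(ADP-ribose) polymerase gene Parp1 (-0.04, adjusted p = 0.808), the p38 kinase gene Mapk14 (0.03) and Stat3 (-0.23, adjusted p = 0.0534) did not pass. The DNA repair gene Lig4 rose by 0.56 (adjusted p = 0.00125). Of the 27 genes of its list, 2 were higher and 4 lower at an unadjusted p under 0.05. Of the atrial markers, 7 of 8 lay above control and passed when adjusted over the list alone, Bmp10 being the only 1 over all genes (1.77 ± 0.43, adjusted p = 0.0466, a call that ended in 8 of the 10 fits that left out 1 array). The Bmp10 change was 0.69 without control replicate 2 and 2.85 without control replicate 1. Among fibroblast markers 3 of 11 rose (4 adjusted over the list alone), with Dcn at 0.36 ± 0.05. That count depended on single arrays, and without control replicate 2 more of these markers fell than rose.

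In total, 362 of 14324 genes changed after 2 days of heat, 95 higher and 267 lower. The set test camera called 16 of 38 lists. Of the lists named above, cell cycle (adjusted p = 0.0211 with an estimated correlation), ribosomal proteins (0.0211), core histones (0.0314) and glycolysis (0.046) held with an estimated correlation. The calls were lost there for heat shock (adjusted p = 0.0676 with an estimated correlation), linker histones (0.106), fatty acid oxidation (0.407), glucocorticoid-responsive genes (0.256), atrial markers (0.276) and fibroblast markers (0.372, and 0.34 by camera without control replicate 2). The total was 78 without AC2d replicate 1, 90 without AC2d replicate 2 and 633 without control replicate 1, and the 21 cell cycle genes became 8 and 9 without those AC2d pools. Without AC2d replicate 1 the 7 core histone genes became 4, and without either AC2d pool the 5 glycolysis genes became 2.

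**Figure D2:**
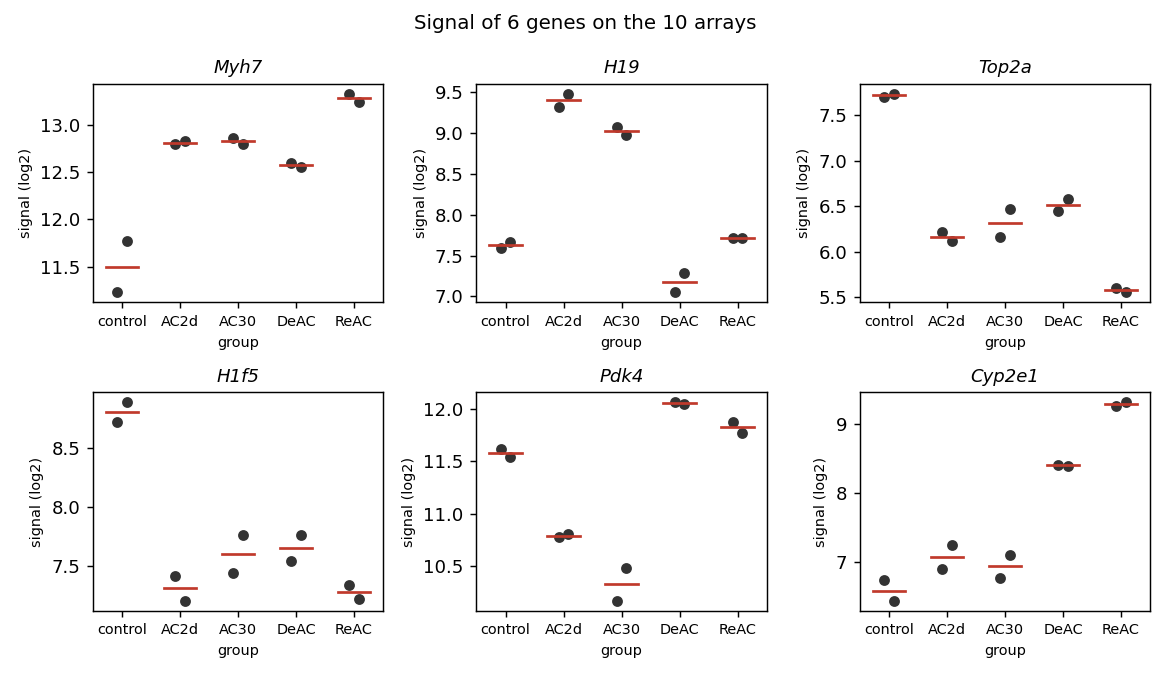
Log2 signal (vertical axis) of Myh7, H19, Top2a, H1f5, Pdk4 and Cyp2e1 in the 5 groups (horizontal axis), with a point for each pool and a line at the mean of the 2 pools. Against control, Top2a changed by -1.55 in AC2d, -1.40 in AC30, -1.20 in DeAC and -2.14 in ReAC, and Pdk4 by -0.79 in AC2d, -1.25 in AC30 and 0.48 in DeAC.

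After 30 days of heat, compared with younger untreated rats, the chemokine Cxcl13 rose by 2.05 ± 0.14 (n = 2 pools per group, adjusted p = 4.85e-06), Myh7 by 1.33 ± 0.11 (adjusted p = 1.74e-05) and the muscle enolase Eno3 by 0.67 ± 0.05 (adjusted p = 4.85e-06). Inha fell by 1.85 ± 0.09 (adjusted p = 1.81e-07), Top2a by 1.40 ± 0.11, the lipoxygenase Alox15 by 1.33 ± 0.11 and Pdk4 by 1.25 ± 0.08 (adjusted p = 1.81e-06). Of 28 fatty acid oxidation genes, 19 fell and 9 did not pass (21 fell adjusted over the list alone), with Cpt2 at -0.45 ± 0.06 and Acaa2 at -0.34 ± 0.04. Of 81 oxidative phosphorylation genes, 24 fell, 1 rose and 56 did not pass (32 fell and 2 rose adjusted over the list alone), Ndufv1 at -0.23 ± 0.04 being among those that fell. Cell cycle genes fell in 19 of 34 cases (25 adjusted over the list alone). Of the 76 genes matching the pattern for ribosomal proteins, 21 rose, the kinase gene Rps6ka2 among them, and 55 did not pass (29 rose adjusted over the list alone), with Rps20 at 0.34 ± 0.05 and Rpl31 at 0.30 ± 0.05. Of 18 glucocorticoid-responsive genes, 9 fell and 1 rose (11 and 2 adjusted over the list alone), the cell cycle inhibitor Cdkn1a at -0.79 ± 0.09 and Nfkbia at -0.74 ± 0.10 among them. The oxygen sensor gene Egln3 fell by 0.58 ± 0.05. Core histones fell in 7 of 22 cases and rose in 1 (8 and 4 adjusted over the list alone), H2ac4 at -0.72 ± 0.11 among them, and H1f1 fell by 1.12 ± 0.10.

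Markers of atrial tissue and of several cell types moved with these genes. Of 8 atrial markers, 7 rose and 1 fell, over all genes and adjusted over the list alone, including Sln (2.28 ± 0.53, adjusted p = 0.0169, but 0.116 without AC30 replicate 1 and 0.0592 without AC30 replicate 2) and Bmp10 (2.24 ± 0.43, adjusted p = 0.0057, but 0.0611 without AC30 replicate 1). The hepcidin gene Hamp (2.37 ± 0.48, adjusted p = 0.00846, but 0.0805 without AC30 replicate 1) and Mybphl (2.16 ± 0.46, adjusted p = 0.0102, but 0.0813 without AC30 replicate 1) rose as well. Rxfp1, the relaxin receptor, rose by 1.99 ± 0.33, and by 1.18 without control replicate 2. The Sln change was 0.93 without control replicate 2 and 3.64 without control replicate 1, and the Bmp10 change was 1.16 without control replicate 2. Of 9 endothelial markers 7 fell (8 adjusted over the list alone), Tie1 at -0.35 ± 0.07. Of 11 fibroblast markers 5 rose (6 adjusted over the list alone), Tcf21 at 0.67 ± 0.08, Lum at 0.53 ± 0.06 and Dcn at 0.43 ± 0.05, and the mesothelial markers Krt19 (0.77 ± 0.11) and Msln (0.66 ± 0.10) rose. Among adipocyte markers, 2 of 10 fell and 0 rose in limma, over all genes and adjusted over the list alone. The direction turned on single control pools, since 5 rose and 1 fell without control replicate 1, while 0 rose and 5 fell without control replicate 2, and 1 fell without either AC30 pool.

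The AC30 group differed from control in 1222 genes, 512 higher and 710 lower, and camera called 16 of 38 lists. Cell cycle (adjusted p = 0.0488 with an estimated correlation) and ribosomal proteins (0.046) held with an estimated correlation. Fatty acid oxidation, glucocorticoid-responsive genes, core histones, linker histones and mesothelial markers did not (adjusted p = 0.166 each with an estimated correlation), nor did oxidative phosphorylation, endothelial, atrial and fibroblast markers (0.2 each). Without AC30 replicate 1 the total was 481, with 11 cell cycle, 9 fatty acid oxidation and 4 oxidative phosphorylation genes falling, 6 genes of the ribosomal list rising, 2 endothelial markers falling, and 3 each of the atrial and fibroblast markers rising. Without control replicate 2 it was 696, with 11 oxidative phosphorylation genes and 1 endothelial marker falling and 13 genes of the ribosomal list rising, and without AC30 replicate 2 there were 4 atrial markers and no camera call of core histones (adjusted p = 0.0644) or linker histones (0.115). With the mean atrial marker level as a covariate, an alternative chosen after seeing the data, 218 genes passed.

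**Figure D3:**
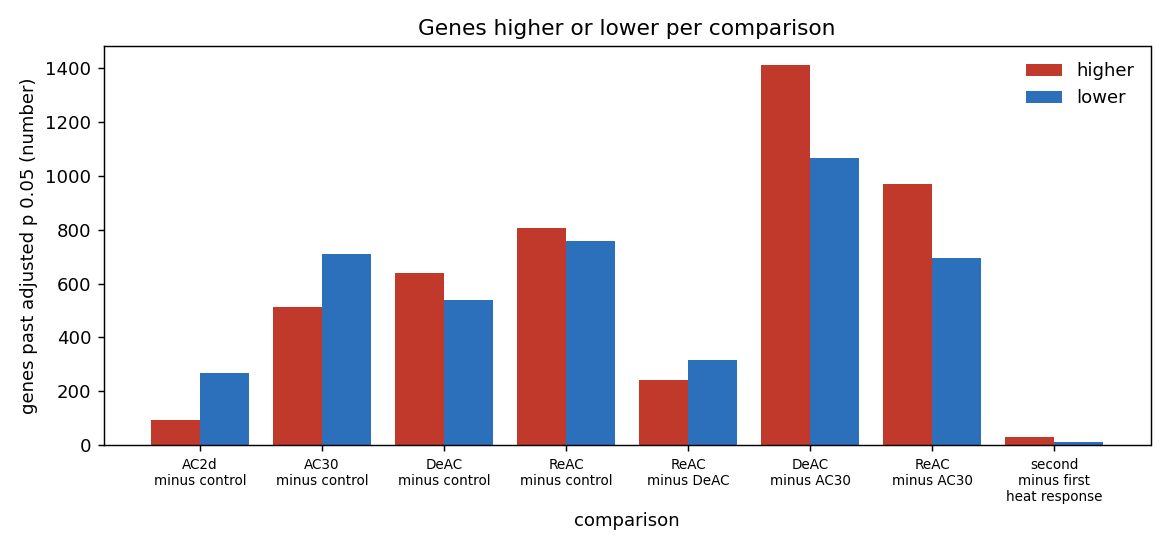
Number of genes higher and lower at adjusted p under 0.05 (vertical axis, of 14324 genes) in each of 8 comparisons (horizontal axis). DeAC against AC30 had the highest total (1411 higher and 1067 lower), and the second response minus the first the lowest (32 and 11).

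The deacclimated group, 30 days after the heat ended, was compared with control to ask what outlasts the treatment, although it was also 2 months older. The cytochrome P450 gene Cyp2e1 rose by 1.83 ± 0.13 (n = 2 pools per group, adjusted p = 7.37e-06), the opioid precursor Penk by 1.13 ± 0.09, Myh7 by 1.07 ± 0.11 (adjusted p = 9.15e-05), Myo16 by 1.07 ± 0.11 and the epoxide hydrolase Ephx2 by 1.04 ± 0.09. Matrix genes fell, with 20 of 32 lower, 1 higher and 11 not passing (23 lower and 1 higher adjusted over the list alone). Periostin (Postn) fell by 1.59 ± 0.14 (adjusted p = 3.09e-05), the collagen genes Col1a1 by 1.10 ± 0.11 and Col3a1 by 0.92 ± 0.06, fibrillin Fbn1 by 0.63 ± 0.05 and Sparc by 0.41 ± 0.04. Cell cycle genes fell in 19 of 34 cases (21 adjusted over the list alone), Top2a by 1.20 ± 0.11. Core histones fell in 7 of 22 cases and 15 did not pass (15 fell adjusted over the list alone), H2ac4 by 0.75 ± 0.11, and the linker histones H1f5 and H1f1 fell by 1.15 ± 0.12 and 1.05 ± 0.10. Fatty acid oxidation genes moved the other way from AC30, with 12 of 28 higher and 1 lower (23 and 1 adjusted over the list alone). The atrial marker Sln was highest in the AC30 pools and lowest in the DeAC pools. Whether a differing share of atrial tissue added to this turn, or to the fall of the matrix genes, was not tested for these lists. The uncoupling protein gene Ucp3 rose by 0.84 ± 0.12, the carnitine carrier Slc25a20 by 0.34 ± 0.05 and Pdk4 by 0.48 ± 0.08, while Ucp2 fell by 0.42 ± 0.05. The glucocorticoid-responsive genes Zbtb16 (0.81 ± 0.05, adjusted p = 6.75e-06) and Fkbp5 (0.72 ± 0.12) rose with 4 others of 18, and 1 fell (8 and 1 adjusted over the list alone). The small heat shock gene Hspb8 rose by 0.29 ± 0.04 and Hspa4l by 0.55 ± 0.09. Hcn4 rose by 0.68 ± 0.08.

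Pathways that the study itself brought forward were covered by lists for the p38 and Jak-Stat and PI3K-Akt pathways, DNA repair with poly(ADP-ribose) polymerases, linker and core histones, and chromatin modifiers. The study chose these on the same samples, so their list-alone counts and camera calls are not independent evidence in any comparison here. This includes the calls of core histones that held with an estimated correlation. In DeAC against control 3 of 26 p38 genes rose (10 adjusted over the list alone), namely Dusp1 (0.42 ± 0.08, adjusted p = 0.00551, but 0.0789 without DeAC replicate 2), Mknk2 (0.30 ± 0.06, adjusted p = 0.00747, but 0.0771 without DeAC replicate 2) and Mapkapk2 (0.21 ± 0.05, adjusted p = 0.0164, but 0.126 without DeAC replicate 1 and 0.0925 without control replicate 1). The count of 3 became 1 without DeAC replicate 2 and 5 without either AC30 pool. Mapk14 itself did not pass (0.25, adjusted p = 0.06). The PI3K subunit gene Pik3r1 rose by 0.27 ± 0.05 (adjusted p = 0.00675, but 0.0817 without DeAC replicate 2) with 2 more of 21 genes of its list (5 adjusted over the list alone), a count that was between 0 and 4 when single arrays were left out, and Akt1 did not pass (0.07). In the limma test 0 of 24 Jak-Stat genes passed, with 5 at an unadjusted p under 0.05. DNA ligase gene Lig4 rose by 0.74 ± 0.08 (adjusted p = 8.34e-05), and Parp1 did not pass (0.13, adjusted p = 0.115). The histone methyltransferase gene Ezh2 fell by 0.53 ± 0.10 (adjusted p = 0.00476, but 0.0583 without DeAC replicate 2). Of these lists, camera called p38 and linker histones, both calls being lost with an estimated correlation (adjusted p = 0.159 and 0.0914), and core histones, which held there (0.0404).

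In the same comparison Bmp10 fell by 4.84 ± 0.43, Sln by 4.82 ± 0.53, Myl7 by 3.92 ± 0.43 and the natriuretic peptide gene Nppa by 2.82 ± 0.28 (adjusted p = 7e-05), which were the 4 of 8 atrial markers that fell, while 1 rose, over all genes and adjusted over the list alone (7 fell without control replicate 2). Mybphl fell by 2.71 ± 0.46, or by 1.56 without control replicate 1, but with the atrial covariate chosen after seeing the data it rose by 1.08 (adjusted p = 0.0417). The mesothelial marker Msln fell by 0.83 ± 0.10, and 2 of 10 adipocyte markers fell (3 adjusted over the list alone). Without control replicate 2 there were 6, without an AC2d or a ReAC pool 1, and without either DeAC pool or control replicate 1 there were 0. Macrophage markers rose in 5 of 16 cases (6 adjusted over the list alone), Lyz2 by 0.42 ± 0.08 and Cd74 by 0.27 ± 0.05, with 3 rising without either DeAC pool. The immediate-early gene Ccn1 rose by 0.73 ± 0.11. Camera called markers of stromal and vessel cells lower, and these calls were lost with an estimated correlation (adjusted p = 0.426 for fibroblast, 0.116 for smooth muscle and pericyte and 0.298 for endothelial markers). Of 11 fibroblast markers 3 fell and 2 rose (6 and 2 adjusted over the list alone), with 5 falling without control replicate 2, 1 rising without DeAC replicate 2, and the call ending by camera without DeAC replicate 1 (0.0797) and control replicate 1 (0.135). Of 9 smooth muscle and pericyte markers 1 fell (5 adjusted over the list alone), with 0 without DeAC replicate 1, 3 without either AC30 pool and 4 without control replicate 2. Of 9 endothelial markers 3 fell (6 adjusted over the list alone), with 1 without DeAC replicate 2, and that call ended by camera without control replicate 2 (0.0688).

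A total of 1178 genes separated DeAC from control, 638 higher and 540 lower, and camera called 20 of 38 lists. Core histones held with an estimated correlation (adjusted p = 0.0404). The calls were lost there for matrix, cell cycle, linker histone, macrophage and mesothelial lists (adjusted p = 0.0914 each with an estimated correlation), fatty acid oxidation and glucocorticoid-responsive genes (0.159 each) and atrial and adipocyte markers (0.24 each, the adipocyte call also ending by camera at 0.153 without control replicate 1). Without DeAC replicate 2 the total was 464, with 12 cell cycle genes falling and 5 fatty acid oxidation and 3 glucocorticoid-responsive genes rising, and without DeAC replicate 1 it was 683 with 11 cell cycle genes. Scaling each array to its median gave 985 higher and 217 lower in place of 638 and 540, and the fit with the atrial covariate chosen after seeing the data gave 214 genes.

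After the second 2 days of heat, the reacclimated group was compared with control. Cyp2e1 rose by 2.72 ± 0.13 (n = 2 pools per group, adjusted p = 1.89e-07), Myh7 by 1.78 ± 0.11 (adjusted p = 5.56e-07), the aldehyde oxidase Aox3 by 1.78 ± 0.22, the interferon-induced Mx1 by 1.61 ± 0.15 (adjusted p = 1.44e-05) and Ankrd23, a muscle ankyrin repeat gene, by 1.58 ± 0.11. Top2a fell by 2.14 ± 0.11 (adjusted p = 2.66e-07), Alox15 by 1.93 ± 0.11, Inha by 1.67 ± 0.09 and H1f1 by 1.54 ± 0.10, and the fast heart myosin gene Myh6 fell by 0.33 ± 0.03 (adjusted p = 3.24e-05). Cell cycle genes fell in 24 of 34 cases (25 adjusted over the list alone) and core histones in 11 of 22 (11 adjusted over the list alone), H2ac4 by 1.11 ± 0.11. Matrix genes fell in 16 of 32 cases and rose in 3 (18 and 4 adjusted over the list alone), Col5a1 by 0.88 ± 0.07 and Fbn1 by 0.82 ± 0.05. Interferon-response genes rose in 12 of 26 cases (14 adjusted over the list alone), Irf7 by 0.90 ± 0.11 and Usp18 by 0.91 ± 0.12. Macrophage markers rose in 12 of 16 cases (14 adjusted over the list alone), Lyz2 by 0.86 ± 0.08, Cd163 by 0.75 ± 0.10 and the complement gene C1qa by 0.69 ± 0.10, and lymphocyte markers in 6 of 12 (8 adjusted over the list alone), Cd3g by 0.83 ± 0.12. The steroid receptor chaperone Fkbp5 rose by 1.28 ± 0.12 and Zbtb16 by 0.91 ± 0.05, and heme oxygenase Hmox1 rose by 0.75 ± 0.09. Among the pathways brought forward by the study, Mapk12 rose by 0.74 ± 0.07 (adjusted p = 2.91e-05), Pik3r1 by 0.51 ± 0.05, Lig4 by 0.69 ± 0.08 and Jak2 by 0.43 ± 0.07, and Parp1 did not pass (-0.13, adjusted p = 0.101). Atrial markers rose in 1 of 8 cases over all genes and adjusted over the list alone, and in 0 without either ReAC pool. The direction turned on the control pools, since 7 rose and 0 fell without control replicate 1, while 1 rose and 6 fell without control replicate 2.

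The reacclimated group differed from control in 1564 genes, 807 higher and 757 lower, and camera called 13 of 38 lists. Cell cycle, macrophage and core histone lists held with an estimated correlation (adjusted p = 0.0366 each), and the calls were lost there for the interferon response (adjusted p = 0.206 with an estimated correlation), matrix and lymphocyte lists (0.143 each). Without ReAC replicate 2 the total was 665 and 1 lymphocyte marker passed, and without ReAC replicate 1 it was 678 and 3 did. Scaling to the median gave 997 higher and 339 lower.

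**Figure D4:**
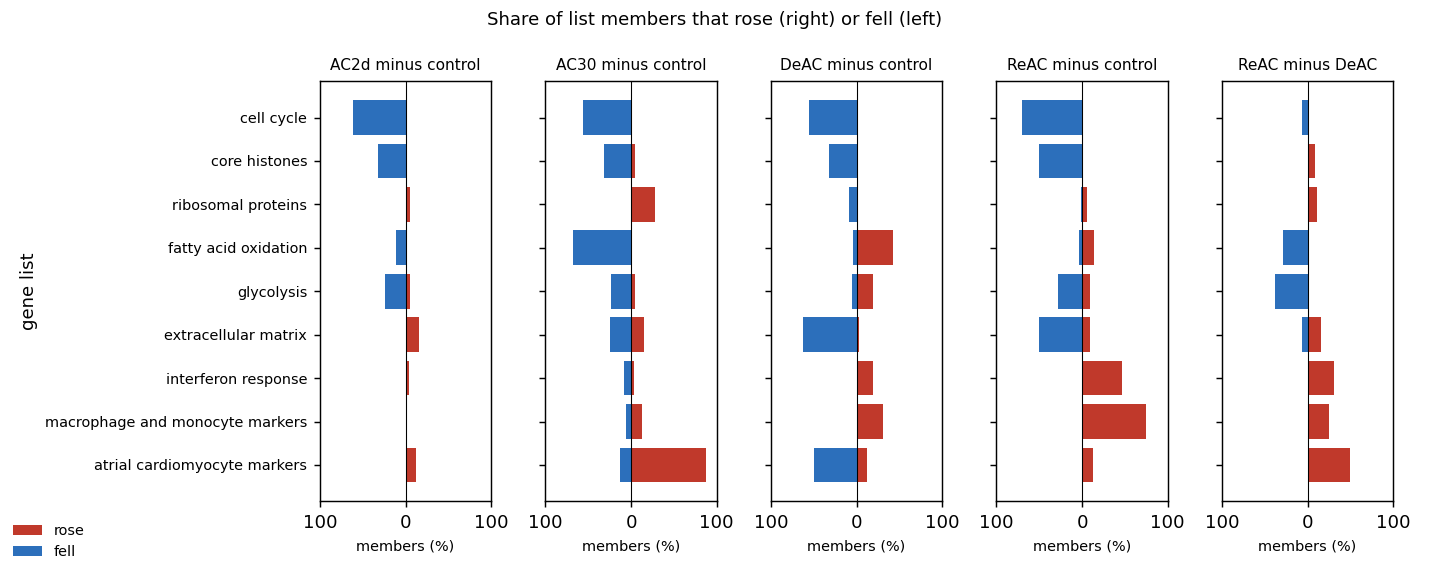
Percentage of the measured members of 9 gene lists (vertical axis) that rose (bars to the right) or fell (bars to the left) in 5 comparisons. Of 34 cell cycle genes 21 fell in AC2d and 24 in ReAC against control, and of 28 fatty acid oxidation genes 19 fell in AC30 while 12 rose in DeAC, whereas the mean of the ribosomal list in DeAC was -0.027 here and 0.078 with scaling to the median.

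The second heat response itself was measured as ReAC against DeAC, 2 groups of the same age and history apart from the last 2 days. The lipase-family gene Pnpla3 fell by 1.30 ± 0.12 (n = 2 pools per group, adjusted p = 0.000119), Ucp3 by 1.19 ± 0.12 (adjusted p = 0.000127), the transferrin receptor gene Tfrc by 1.19 ± 0.08 (adjusted p = 1.99e-05), the ketone body enzyme Bdh1 by 1.02 ± 0.11, Inha by 0.99 ± 0.09, Ephx2 by 0.97 ± 0.09 and Top2a by 0.94 ± 0.11. Mapk12 rose by 0.53 ± 0.07 (adjusted p = 0.00169) and Myh7 by 0.71 ± 0.11 (adjusted p = 0.0039, but 0.06 without ReAC replicate 1), while Myh6 fell by 0.30 ± 0.03 (adjusted p = 0.000274). Interferon-response genes rose in 8 of 26 cases (17 adjusted over the list alone), a count that became 0 without DeAC replicate 1, 4 without DeAC replicate 2, 1 without either ReAC pool and 13 without control replicate 1. Glycolysis genes fell in 8 of 21 cases (12 fell and 1 rose adjusted over the list alone), and 0 fell without DeAC replicate 2 or either ReAC pool, 2 without DeAC replicate 1 and 5 without either AC2d pool. Fatty acid oxidation genes fell in 8 of 28 cases (14 fell and 1 rose adjusted over the list alone), with 2 or 3 falling when a DeAC or ReAC pool was left out and 5 without either AC2d pool. Macrophage markers rose in 4 of 16 cases (7 adjusted over the list alone), a count that lay between 0 and 5 when single arrays were left out. Parp1 fell by 0.26 ± 0.05 (adjusted p = 0.00866, but 0.0807 without DeAC replicate 1, 0.0713 without ReAC replicate 1 and 0.0991 without ReAC replicate 2).

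Atrial markers rose with these genes in 4 of 8 cases (5 adjusted over the list alone, and 7 over all genes without either control pool), namely Sln by 5.68 ± 0.53 (adjusted p = 0.000112), Bmp10 by 5.09 ± 0.43, Myl7 by 4.31 ± 0.43 and Nppa by 3.25 ± 0.28. The mesothelial marker Msln rose by 0.78 ± 0.10 (adjusted p = 0.00077). Of 9 genes of the hypertrophy and fetal heart list that rose, of 18, some are atrial genes such as Nppa, and Ankrd1 rose by 0.31 ± 0.04 (9 rose and 3 fell adjusted over the list alone, and 5, 5, 3 and 4 rose over all genes without DeAC replicate 1, DeAC replicate 2, ReAC replicate 1 and ReAC replicate 2). In total 560 genes changed, 244 higher and 316 lower, and camera called 14 of 38 lists. With an estimated correlation 0 of these 14 held, against 9 of 38 at an unadjusted p under 0.05. The values there were adjusted p = 0.0568 for glycolysis, 0.0812 for macrophage, mesothelial and hypertrophy lists, 0.17 for the interferon response and atrial markers, and 0.228 for fatty acid oxidation. The total fell to 98 without ReAC replicate 1, 132 without ReAC replicate 2, 177 without DeAC replicate 2, 202 without DeAC replicate 1, 362 without AC2d replicate 1 and 361 without AC2d replicate 2, and rose to 866 and 863 without control replicates 1 and 2. The fit with the atrial covariate chosen after seeing the data gave 122 genes.

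The first response (AC2d against control) and the second (ReAC against DeAC) share no array. Of the genes called in each, 36 were higher in both and 105 lower in both, where 1.62 and 5.89 would be expected if the calls were independent, and 4 went opposite ways. Across genes the Pearson correlation of the log2 changes was 0.392 and the Spearman correlation 0.282, though genes are not independent replicates. The Pearson value was 0.181 without control replicate 2 and 0.462 without control replicate 1. The mean change of the atrial markers was 0.849 in the first response and 2.379 in the second. A differing share of atrial tissue could therefore add to the likeness, which was not tested. Both tests also took the spread of a gene from all 10 arrays, so the calls are not fully independent. Genes that responded differently were tested as the second response minus the first. Rats of the second response were also older, so age and earlier acclimation cannot be told apart in this test. H19 rose by 1.78 in the first and by 0.54 in the second, a difference of -1.23 ± 0.12 (adjusted p = 4e-04). Ankrd23 did not pass in the first (-0.22) and rose by 1.37 in the second, a difference of 1.60 ± 0.15 (adjusted p = 4e-04). The insulin-like growth factor binding protein gene Igfbp3 differed by -0.81 ± 0.09 (adjusted p = 0.00263) and Spetex2el3 by -1.30 ± 0.13 (adjusted p = 4e-04). These 4 passed in all 10 fits that left out 1 array. Postn differed by 1.59 ± 0.20 (adjusted p = 0.00385, but 0.0558 without AC2d replicate 1).

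In that test 43 of 14324 genes passed, 32 higher and 11 lower in the second response. The number was 6 and 7 without AC2d replicates 1 and 2, 8 and 14 without DeAC replicates 1 and 2, 9 and 7 without ReAC replicates 1 and 2, and 118 and 198 without control replicates 1 and 2. Camera called 12 of 38 lists, among them cell cycle with a mean difference of 0.355, for which 0 of 34 genes passed in limma over all genes (16 at an unadjusted p under 0.05, 14 adjusted over the list alone). None of the 12 held with an estimated correlation (0 of 38, against 8 at an unadjusted p under 0.05, and cell cycle at adjusted p = 0.119 with an estimated correlation). Camera also called atrial markers (mean difference 1.53) higher in the second response, with adipocyte (0.66), smooth muscle and pericyte (0.31) and mesothelial markers (0.27). With an estimated correlation these calls were lost at adjusted p = 0.42, 0.464, 0.224 and 0.203. Of 8 atrial markers 2 passed, Bmp10 and Nppa (4 adjusted over the list alone), with 0 passing when any 1 array of AC2d, DeAC or ReAC was left out, 1 without either AC30 pool, 4 higher and 2 lower without control replicate 1 and 4 higher without control replicate 2. The adipocyte call ended by camera without AC2d replicate 1 (0.0712), DeAC replicate 2 (0.0877), ReAC replicate 2 (0.0872) and control replicate 1 (0.906). The smooth muscle and pericyte call ended without AC2d replicate 1 (0.0706), DeAC replicate 1 (0.0543), ReAC replicate 1 (0.0532) and control replicate 1 (0.163), and the mesothelial call without AC2d replicate 1 (0.107) and DeAC replicate 1 (0.0999). The atrial covariate chosen after seeing the data gave 134 genes, 46 higher and 88 lower, so that the balance of directions depended on the fit. All probe sets gave 39 higher and 120 lower, of which 6 and 103 were probe sets with no single gene symbol.

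**Figure D5:**
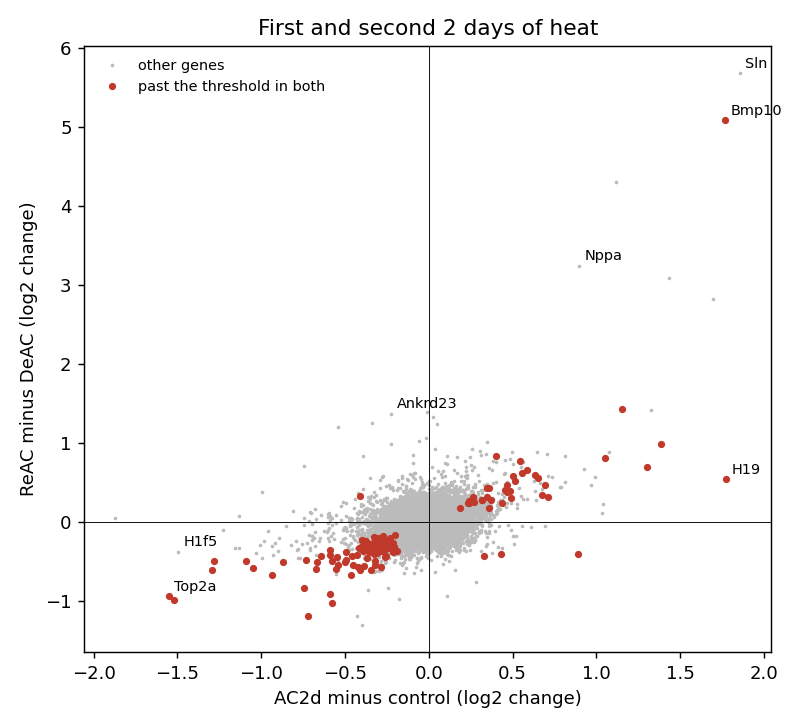
Log2 change in the first heat response (horizontal axis, AC2d minus control) against that in the second (vertical axis, ReAC minus DeAC), with a point for each gene and the genes called in both (141 the same way and 4 opposite ways) marked in red. Top2a lay at -1.55 and -0.94, H19 at 1.78 and 0.54, and Ankrd23 at -0.22 and 1.37.

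The fate of the 30-day changes after the heat ended was followed in DeAC against AC30, where Pdk4 rose by 1.73 ± 0.08 (n = 2 pools per group, adjusted p = 3.62e-08), Bdh1 by 1.97 ± 0.11 and the phospholipase gene Pla2g7 by 1.53 ± 0.10. Sln fell by 7.11 ± 0.53 and Bmp10 by 7.08 ± 0.43, with 7 of 8 atrial markers lower and 1 higher. Of the 1222 genes called in AC30 against control, 810 (66.3%) moved the opposite way in DeAC against AC30, 199 were still called the same way in DeAC against control (66 higher and 133 lower), 15 were in both counts and 228 in neither. Both comparisons use the AC30 pools, whose error favours such a move. A differing share of atrial tissue in the AC30 and DeAC pools could favour it too, which was not tested for the 810. In 20 simulated data sets that kept the AC30 means and had no change from AC30 to DeAC, a mean of 1.44% of the AC30 calls went the opposite way at the p of the real calls. The simulated means already held measurement error and gave a mean of 2420 AC30 calls, so this share may be too low. Errors were drawn separately for each gene, so a shift of tissue shared by many genes was not simulated. Those 199 compare with 22.8 higher and 26.8 lower expected if calls were independent, but the comparisons share the control pools, whose error favours calls the same way. In 20 simulated data sets without any effect, a mean of 0.15 and at most 1 gene were called the same way in both. That amount was not measured for data with real changes. A further 140 genes were called in both with opposite directions, and across genes, which are not independent replicates, the Pearson correlation was 0.0862 and the covariance 0.00353. Simulated data without any effect gave a Pearson correlation of 0.501 and a covariance of 0.00569 through the shared control alone. The real Pearson and covariance values therefore show no likeness of the changes beyond that. They do not exclude a likeness either, because genes that moved opposite ways, such as the atrial markers Sln and Bmp10, lower both values. The Spearman correlation was 0.202, for which no simulated value was available. Top2a, Myh7 and H1f5 were among those called the same way in both. In total 2478 genes changed from AC30 to DeAC, 1411 higher and 1067 lower. Camera called 19 of 38 lists, of which 0 held with an estimated correlation, against 13 at an unadjusted p under 0.05. The total was 1445 without AC30 replicate 1 and 1527 without DeAC replicate 2, scaling to the median gave 1909 higher and 456 lower, and the atrial covariate chosen after seeing the data gave 99 genes.

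Reacclimated and 30-day hearts were compared as well. In ReAC against AC30, Cyp2e1 rose by 2.36 ± 0.13 (n = 2 pools per group, adjusted p = 1.88e-07), Ankrd23 by 1.73 ± 0.11 and Reg3b by 1.72 ± 0.16, and Cxcl13 fell by 1.66 ± 0.14. Fibroblast markers fell in 7 of 11 cases and rose in 1 (9 and 1 adjusted over the list alone), and atrial markers fell in 4 of 8 and rose in 1 (7 and 1 adjusted over the list alone, and 7 fell over all genes without either control pool). Of the 1222 genes called in AC30, 398 were called the same way in ReAC against control. In total 1665 genes changed between ReAC and AC30, 970 higher and 695 lower, or 1263 and 283 with scaling to the median. Camera called 18 of 38 lists, of which 0 held with an estimated correlation, against 9 at an unadjusted p under 0.05. The total was 747 without ReAC replicate 1, 769 without ReAC replicate 2, 779 without AC30 replicate 1 and 811 with the atrial covariate chosen after seeing the data.

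A fold table was available beside the array values. The authors' deposited table listed 651 probe sets, each at least 1.5-fold away from control in some group. Of its entries of at least 1.5-fold for named genes, 85 of 118 for AC2d, 198 of 207 for AC30, 159 of 199 for DeAC and 294 of 326 for ReAC were in the authors' deposited table and were also called here.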

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

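The tests of atrial tissue, fat tissue and cell cycle genes in this part were all chosen after those results were seen, while the test of the second heat response against the first was planned.

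The response to 2 days of heat differed between rats with and without earlier acclimation for 43 genes, by a test of the difference itself. The second response was measured at 3 months of age and the first at 1 month, so earlier acclimation cannot be told apart from age here. Of the genes named by rule, the second response exceeded the first, in log2 units, by 3.31 for Bmp10, 2.35 for Nppa, 1.60 for Ankrd23, 1.59 for Postn, 1.41 for Tceal7, 1.31 for Reg3b, 1.19 for the metallothionein gene Mt2A, 1.12 for H1f5, 0.80 for H2bc18, 0.66 for Hist2h3c2 and 0.53 for Zbtb16. It lay below the first for Spetex2el3 (-1.30), H19 (-1.23), Myo16 (-1.03), Cacna1h (-0.83), Igfbp3 (-0.81), Ephx2 (-0.80), Lig4 (-0.61) and the immunophilin gene Fkbp4 (-0.41). Bmp10 and Nppa are atrial markers whose control pools lay 2.17 and 1.42 apart, so their differences can come from the share of atrial tissue described further on, which the test of the difference does not separate from a changed response to heat. Only Ankrd23, Spetex2el3, H19 and Igfbp3 of these passed in all 10 fits that left out 1 array, and the total of 43 lay between 6 without AC2d replicate 1 and 198 without control replicate 2. It was 7 without AC2d replicate 2 or ReAC replicate 2, 8 and 14 without DeAC replicates 1 and 2, 9 without ReAC replicate 1 and 118 without control replicate 1.

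Signal outside the named genes also differed between groups. Of 12245 probe sets with no single gene symbol, 1442 differed among the 5 groups. In AC2d against control 252 of them changed, 178 higher and 74 lower. In the second response minus the first 109 changed, 103 of them lower, and 91 of those 103 were called higher in AC2d against control. Their median change was 1.06 in AC2d, 0.18 in AC30 and 0.68 in DeAC against control, and -0.28 in ReAC against DeAC. Among the 103, 21 had the same values as another of them on all arrays, so they do not all count separately.

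Of 8 atrial markers, Bmp10, Sln, Myl7 and Nppa were the 4 that fell in DeAC against control, with Myl7 at 13.20 and 10.97 in the control pools and 8.19 and 8.13 in the DeAC pools, while Dkk3, Kcnj3 and Tbx5 lay near control replicate 2 (Tbx5 at 8.49 and 8.40, against 8.41) and Kcna5 rose. Scaling does not account for this, because the median change of the 8, which was -1.56, was still -1.44 under the scaling that gave the smallest. Across the 8 markers the gap between the control pools went with the change from AC30 to DeAC (Pearson r 0.98, across genes that are not independent replicates, and the comparisons share no array), as a smaller share of atrial tissue in the DeAC pools would give. All 8 markers had a larger gap between the control pools than between the pools of any other group, a gap to which deacclimation cannot have led. Whether these genes also changed in heart cells with deacclimation cannot be told apart from that share, since no array measured the tissues separately and 6 of the 8 lay above the median gene of each DeAC array.

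Of 10 adipocyte markers, Ucp1, Pck1, Adipoq, Cidec and Plin1, picked here after their values were seen, were high in control replicate 1 and in both AC30 pools, with Pck1 at 8.58 and 5.92 in the control pools and 7.66 and 7.68 in the AC30 pools. Fabp4 and Lipe were lower in the AC30 pools (10.68 and 10.72, 8.37 and 8.35) than in either control pool (11.06 and 10.86, 8.66 and 8.77). Heat for 30 days as the only cause is excluded, because the untreated control replicate 1 lay above control replicate 2 by 3.92 log2 units for Ucp1. Fat tissue taken along with some hearts is a candidate explanation, and of 14 measured genes in a further list of fat genes, 6 were higher in control replicate 1 than in replicate 2 by more than their gap in any other group. It cannot be told apart from differences between animals, since in control replicate 2, where the pattern was absent, 2 of 10 adipocyte markers and 6 of the 14 further genes lay above the median gene (Fabp4 at 10.86 and Cox8b at 11.25), levels in the heart that would hide a small share of fat.

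The mean change of the cell cycle list against control was -0.592 in AC2d, -0.529 in AC30, -0.414 in DeAC and -0.652 in ReAC. In each group some of its 34 genes did not pass, and camera's call in DeAC was lost with an estimated correlation. A difference of whole months in age is excluded as the only cause. The mean change of the list after 2 days, at matched labelled age, was 112% of that after 30 days. The labels do not give ages in days, so a gap of days between control and AC2d was not tested. A single unusual control pool is excluded as well, since the mean change after 2 days was still -0.567 without control replicate 1, and the control pools lay 0.049 apart. A mean change of -0.238 in ReAC against DeAC, also at matched age, is consistent with lower cell cycle expression after 2 days of heat, though 2 of 34 genes fell there over all genes (1 without DeAC replicate 2 or ReAC replicate 1) and camera's call (adjusted p = 2.69e-08) was lost with an estimated correlation (0.116). Cells other than heart muscle cells, and an effect of age beside that of heat in AC30, DeAC and ReAC, stay open and were not tested.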

How the results depend on the processing

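Of the alternatives in this part, the fit with the atrial covariate was chosen after the data were seen. No named change that passed in either fit reversed in any of the others, and a change of sign that passed in neither was not counted. Genes named for the largest changes had pools that did not overlap. For these, leaving out 1 array could not reverse a comparison of 2 groups. Of 580 named changes, 523 kept their side of the threshold with the values as deposited, 476 with median scaling, 433 without the trend, 476 with the groups alone, 569 with the mean of the probe sets and 541 with all probe sets, and 475 of 503 did with the dim genes left out. Only 374 of the 580 had passed as reported. Of these calls, 46 were lost with the values as deposited, 94 with median scaling, 146 without the trend, 92 with the groups alone, 5 with the mean of the probe sets and 38 with all probe sets. With 1 array left out it was 5083 of 5800, with the single pool left in a group assumed to vary like those of the other groups. The cause of a move was not tested except where fewer genes, fewer arrays or another threshold make the difference by construction. The values as deposited gave 236 genes in AC2d against control, 365 in ReAC against DeAC and 28 in the second response minus the first. Median scaling gave 149 in AC2d, 602 in AC30 against control, 213 in ReAC against DeAC and 21 in the second minus the first, with a shift of the median gene of at most 0.081 in any comparison. Without the trend there were 105 genes in AC2d, 541 in AC30 and 558 in DeAC against control, 160 in ReAC against DeAC, 1013 in ReAC against AC30, 13 in the second minus the first and 1962 among the 5 groups. All probe sets gave 568 in AC2d and 159 in the second minus the first, 39 of them higher. The groups alone gave 109 in AC2d, 278 in AC30 and 504 in DeAC against control and 1002 in ReAC against DeAC. A 1.5-fold minimum left 89 in AC2d, 207 in AC30, 154 in DeAC and 291 in ReAC against control, 92 in ReAC against DeAC, 406 in DeAC against AC30, 278 in ReAC against AC30 and 470 among the 5 groups. An adjusted p under 0.10 gave 615 in AC2d, 1891 in DeAC, 873 in ReAC against DeAC, 92 in the second minus the first and 337 shared by AC30 and DeAC. Over its 520 probe sets with a gene name, the authors' deposited table had 118, 207, 199 and 326 entries of at least 1.5-fold for AC2d, AC30, DeAC and ReAC. The atrial covariate gave 218 in AC30 and 214 in DeAC against control, 122 in ReAC against DeAC, 99 in DeAC against AC30, 811 in ReAC against AC30, 134 in the second minus the first (46 of them higher, against 32 of 43 in the reported fit) and 2094 among the 5 groups, and of 374 named changes that had passed, 180 passed in the same direction, 189 did not pass and 5 passed in the opposite direction. These 5 were Hamp (-1.95, and 2.14 with the covariate), Mybphl (-2.71, and 1.08) and Adipoq (-1.59, and 1.82) in DeAC against control, and Hamp (2.82, and -1.87) and Mybphl (3.09, and -1.28) in ReAC against DeAC. The covariate is made of genes that themselves differ between the groups, so it can also take away group effects. Its slope rests on differences between the pools within a group, and all 8 atrial markers differed most between the control pools. Those pools also differed in fat and clock genes (Ucp1 by 3.92 and Dbp by 1.79), so the fit does not remove atrial tissue alone. Leaving out the dim genes gave a correlation of 0.503 between the first and second responses. Camera made 128 calls over all comparisons, 10 of them with an estimated correlation, and fry made 136. With 1 array left out the counts ranged from 78 to 633 in AC2d, 481 to 1446 in AC30, 464 to 1374 in DeAC and 665 to 1713 in ReAC against control, 98 to 866 in ReAC against DeAC, 1445 to 2788 in DeAC against AC30, 747 to 2100 in ReAC against AC30, 6 to 198 in the second minus the first and 2263 to 3661 among the 5 groups, and the correlation from 0.181 to 0.462. Correlations of pool differences between groups ranged from -0.077 to 0.21, the highest for AC30 and DeAC. A weak effect shared by pool number is therefore not excluded. A replicate block gave 386 genes in AC2d, 1265 in DeAC against control, 595 in ReAC against DeAC and 52 in the second minus the first. It raised the gene count of every comparison, and moved none by over 1.5 times. Signal near the background of the arrays hides changes of weakly expressed genes.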

Other observations

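The lists in this part were fixed before the data were examined, but which of their values to print was chosen after they were seen, and no explanation was tested here. Of 23 genes of the endoplasmic reticulum stress response, 3 rose in AC30 against control (5 adjusted over the list alone), among them the protein disulfide isomerase Pdia6 (0.40 ± 0.06, n = 2 pools per group, adjusted p = 0.00142), and 7 rising without control replicate 1. In AC2d 1 of the 23 rose (8 rose and 1 fell adjusted over the list alone). That number was 5 without control replicate 1, 2 without AC30 replicate 1 or 2, and 0 without AC2d replicate 1 or 2, DeAC replicate 1 or 2, or control replicate 2. Camera called the list in both (adjusted p = 0.000406 in AC2d and 0.000363 in AC30), and both calls were lost with an estimated correlation (adjusted p = 0.174 and 0.166). In ReAC against control camera did not call it (mean change 0.03, adjusted p = 0.794). In DeAC against AC30 8 of the 23 fell and 1 rose, over all genes and adjusted over the list alone, with 5 falling without DeAC replicate 1, and the mean change of the list was -0.115 there but -0.003 with scaling to the median. Antioxidant genes rose in 8 of 27 cases and fell in 2 in ReAC against control (10 and 4 adjusted over the list alone), with Nqo1 at 0.54 ± 0.10 and the glutathione peroxidase Gpx1 at -0.44 ± 0.08. Without ReAC replicates 1 and 2 the number rising was 4 and 2, and camera's call of the list (adjusted p = 0.305 with an estimated correlation) ended without ReAC replicate 2 (adjusted p = 0.0764 by camera). Of the HIF-1 targets, 3 of 23 fell in AC30 (10 fell and 2 rose adjusted over the list alone), Pdk1 at -0.31 ± 0.04, and 5 fell without AC30 replicate 1. Camera's call of that list (adjusted p = 0.035) was lost with an estimated correlation (0.166), and by camera without AC30 replicate 2 (0.115) and without control replicate 1 (0.269). Of 14 clock genes in AC30, 1 rose and 4 fell, and 2 fell without AC30 replicate 1. Camera's call of the clock genes (adjusted p = 0.035) was lost with an estimated correlation (0.168), and by camera without AC30 replicate 1 (0.0803), AC30 replicate 2 (0.0657) and control replicate 1 (0.8), and the number rising was 3 without control replicate 1 and 0 when any 1 array of AC2d, AC30, DeAC or ReAC was left out. Among them Per1 fell by 0.68 ± 0.10 and Cry2 by 0.46 ± 0.08. The control pools stood apart in clock genes, with Dbp at 9.81 and 8.03, Nr1d1 at 9.69 and 8.43 and Per3 at 8.15 and 6.79.

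Among genes of calcium handling and thyroid hormone response, 8 of 24 rose and 1 fell in DeAC against control (8 and 2 adjusted over the list alone), with malic enzyme Me1 at 0.46 ± 0.05. The mean of this list was -0.06, its median was 0.06 and camera called it higher (adjusted p = 0.00508, or 0.0914 with an estimated correlation), with Sln at -4.82, and with median scaling the mean was 0.03. Of these genes 5 rose without DeAC replicate 2 or without control replicate 1. Erythroid markers fell in 5 of 9 cases in ReAC against control, over all genes and adjusted over the list alone, the anion exchanger Slc4a1 by 0.70 ± 0.12, with 3 and 2 falling without ReAC replicates 1 and 2. Of 14 ventricular heart muscle markers 1 rose and 1 fell in ReAC against control (2 and 2 adjusted over the list alone), with 0 rising without ReAC replicate 1 or 2 and 2 falling without control replicate 1. In AC2d 0 of the 14 passed in limma, where 3 had an unadjusted p under 0.05. Of 8 skeletal muscle markers 0 passed in limma in AC2d, AC30 or ReAC against control, where 1, 0 and 0 had an unadjusted p under 0.05, and 1 fell in DeAC. Schwann cell markers rose in 2 of 7 cases in AC30, and in 1 case without AC2d replicate 1 or 2, AC30 replicate 1 or 2, or control replicate 1 or 2. Of 11 neutrophil and mast cell markers 1 rose in DeAC against control, and 0 without DeAC replicate 1 or 2, ReAC replicate 1 or 2, or control replicate 1.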
